A study of Glycine max with 2 samples.

How the data were processed

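RNA was sequenced from the hypocotyl of soybean (Glycine max) of the line named Williams in the sample titles. One library came from plants inoculated with Phytophthora sojae, an oomycete that causes root and stem rot, and 1 library came from mock-inoculated plants. Per the labels' protocols, plants were grown in a greenhouse, inoculated through the hypocotyl, and their RNA was purified with a plant RNA column kit before Illumina libraries were made with a TruSeq RNA kit. Both titles end in the number 3, and the labels do not say what it stands for. The time between inoculation and harvest is not given in the sources used here.

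The deposited table holds 1 FPKM value (fragments per kilobase of transcript and of library size) per gene and library, as the authors computed it, for 56044 gene models of the soybean annotation Wm82.a2.v1, with the chromosome, start and end of each model. The unit was read from the file's name, which gives it with its letters swapped, and from the values. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq, edgeR, Cuffdiff and Cufflinks were used, with no role given for any of them. Filters, the treatment of reads that map to several places and whether counting used the strand are not given in the sources used here. Per the labels, the kit was a TruSeq RNA kit that is not described as stranded, so reads of a gene and of an overlapping gene on the other strand may not be separable. The table had 0 columns of per-sample values beyond these 2 libraries.

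FPKM is not a count, so no count test was used. With 1 library per condition there is no error between replicates, and no p-value, standard error or test between conditions is given. A difference between the 2 libraries is a description of these libraries and has no replicate check. Each library was mapped to its condition by its column name and sample title. The effect size was log2((inoculated FPKM + 1)/(mock FPKM + 1)), called the log2 ratio, which understates the change of low genes. A gene was counted as expressed at 1 FPKM or more in either library, and as higher or lower in the inoculated library at a log2 ratio of at least 1 in size, a 2-fold difference on this scale. These rules, the chromosome windows and the alternatives were fixed before the data were examined, except where stated.

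The depth of each library is not recorded in the table, but the relative depth can be read from its low values. Where whole reads are counted, a gene's FPKM moves in steps of 1 read, so the ratio of a low gene's values between libraries takes few values. A kernel density (width 0.03) of the log2 ratio without a pseudocount was taken over the 1991 genes above 0 and under 0.3 FPKM in both libraries, and its highest peak was taken as 1 read in each library. The table gives no transcript lengths, so the counts themselves were not recovered and no counting interval is given.

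Gene IDs are printed without the annotation suffix that the table adds. None of the 56044 IDs matched the reference gene table used here (assembly Glycine_max_v4.0, 59048 genes), which was the only source of names, so 0 of the 35 gene lists fixed by product name could be filled and no gene function is given. The rule for named genes then allowed 2 genes higher and 2 lower: those with the most extreme log2 ratio among genes at 5 FPKM or more in either library. All positions are those of the table, on Wm82.a2.v1, and spans include introns.

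The chromosome windows were set by gene number from memory of where the study's resistance loci had been mapped, with no source used here, from Glyma.03G030000 to Glyma.03G040000 and from Glyma.16G209000 to Glyma.16G217000. They are not the study's own mapped intervals, and with no annotation they hold all genes and not a chosen family. A window's median log2 ratio was placed among 10000 random gene lists of the same size, matched on mean FPKM in 50 bins, and also among all stretches of as many neighbouring expressed genes. A run was a series of at least 4 expressed genes that follow each other along a chromosome and are all higher, or all lower; genes under 1 FPKM in both libraries were passed over. Runs were compared with 1000 shuffles of the calls within chromosomes, and the share of higher genes per chromosome with 10000 circular shifts of the calls along the genome. The analyses of runs, chromosomes and gene span were chosen after the values were seen.

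The calculations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9. The procedures were tested on simulated reads for all 56044 genes. Depth was set at 5000000 reads for a mock library and 2 times that for an inoculated library. With no transcript lengths in the table, gene span, introns included, stood in for length. Spans can be longer than transcripts, so the reads drawn can exceed the depth setting. In either direction, 50 genes were changed at each of 4-fold and 8-fold. The 2-fold rule recovered 100% of each set. The planted changes were well past 2-fold, so this was close to fixed in advance and says nothing about changes near the threshold. The rule called 0.415% of the unchanged expressed genes. The table records neither library depth nor transcript lengths, so this share holds for the simulated settings and is not an error rate for these libraries. Larger counts carry less relative counting noise, so the use of span may have made this share too low. The depth procedure returned a ratio of 2. In a separate simulation all 20 planted runs were found, and shuffles gave at most 1 run. The runs were planted directly as neighbouring calls, so finding them was fixed in advance. Fewer genes were called there than the 2757 called higher in these data, so its shuffle count does not carry over to them. The simulated reads hold counting noise only, with no variation between plants.

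The alternatives were pseudocounts of 0.1 and 5, rescaling to a median ratio of 1 over genes at 5 FPKM or more in both libraries, rescaling to equal totals without the 100 most abundant genes, no filter or a 5 FPKM filter on low values, a 4-fold threshold and random lists without matching. Subtracting the running median over span (1001 genes), leaving out spans under 500 bp, and the comparison of windows with neighbouring stretches were added after seeing the data.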

Results

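Gene expression was measured by RNA sequencing in soybean hypocotyls inoculated with P. sojae and in mock-inoculated hypocotyls, with 1 library per condition. The series title concerns the mapping of a pair of loci for resistance to this pathogen and the genes that lie in them, and the libraries compare expression with and without inoculation. The table covered 56044 gene models, of which 55589 lay on the 20 chromosomes and 455 on scaffolds. In the mock library 40628 genes were above 0 and 32057 reached 1 FPKM. In the inoculated library 42516 genes were above 0 and 32411 reached 1 FPKM. Total FPKM was 660592 in the mock library and 692361 in the inoculated library. No value below has a replicate, so no difference could be tested against the spread between replicates.

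By the measures taken from low values here, the inoculated library was the deeper one. Among 1991 genes under 0.3 FPKM in both libraries, the most frequent log2 ratio of inoculated to mock FPKM was -0.97, and further peaks lay at 0.025, 0.61 and -1.97. These are the places where 2 reads against 1, 3 against 1 and 1 against 2 would fall if the main peak stands for 1 read in each library. Each further peak was sought only near its place, so these positions do not by themselves settle that reading. On that reading the inoculated library held 1.97 times as many mapped fragments as the mock library. A cruder measure gave 1.76: the 5th percentile of FPKM times span in kb was 0.128 over genes above 0 in the mock library alone and 0.0726 over genes above 0 in the inoculated library alone. Of the genes listed at 0 in a single library, 3035 were at 0 in the mock library and 1147 in the inoculated library. Their median in the other library was low, 0.176 FPKM and 0.203 FPKM respectively.

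**Figure D1:**
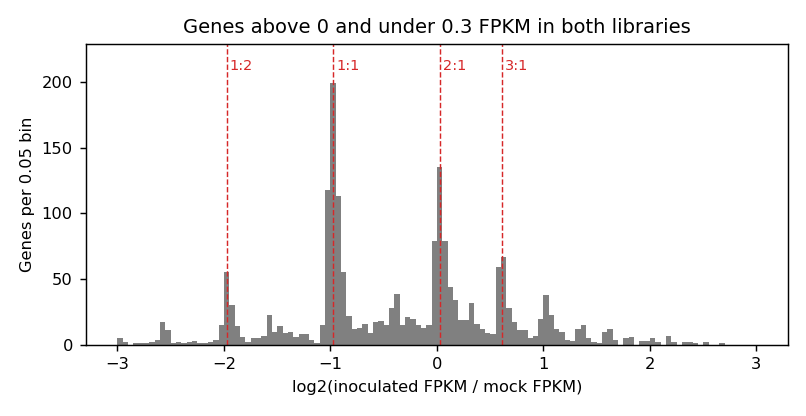
Histogram of the log2 ratio of inoculated to mock FPKM (x axis) for the 1991 genes above 0 and under 0.3 FPKM in both libraries, as genes per 0.05 bin (y axis). Dashed lines mark the main peak at -0.97, read as 1 read in each library, and the places of 2:1, 3:1 and 1:2 reads (inoculated to mock).

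More genes were higher than lower in the inoculated hypocotyl, and the excess grew from 2-fold to 16-fold differences. Of 34062 expressed genes, 2757 (8.09%) were at least 2-fold higher in the inoculated library and 1954 (5.74%) at least 2-fold lower, while 29351 lay within 2-fold. At 4-fold the numbers were 972 higher and 164 lower, at 8-fold 384 and 29, and at 16-fold 142 and 6. Over the 18659 genes at 5 FPKM or more in both libraries, log2 FPKM correlated across genes with a Pearson r of 0.870. The Spearman rho was 0.845. The median log2 ratio of these genes, taken without a pseudocount, was -0.036. Genes are not independent replicates. Genes with a mean of 50 FPKM or more held 301 higher and 212 lower among 2619. Genes with a mean from 10 to 50 FPKM held 785 higher and 644 lower among 10889. From 2 to 10 FPKM there were 1055 higher and 798 lower among 15263. From 0.5 to 2 FPKM there were 616 higher (11.6%) and 300 lower (5.67%) among 5291. Higher genes outnumbered lower ones most in this lowest band, where the depth of the mock library limits the values most. The number of calls depends on the pseudocount: with 5 in place of 1 there were 1349 higher and 687 lower genes, and with 0.1 there were 3529 higher and 3152 lower, so that the share of calls that were higher was 66.3% and 52.8% against 58.5%.

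The gene with the highest log2 ratio was Glyma.02G028600 (chromosome 2, 2604249 to 2605917), which was listed at 0 in the mock library and at 128 FPKM in the inoculated library. Next was Glyma.20G169200 (chromosome 20, 40696468 to 40698879), at 0.947 FPKM in the mock library and 204 FPKM in the inoculated library, 215-fold higher without a pseudocount and a log2 ratio of 6.72. The gene with the lowest log2 ratio was Glyma.20G142000 (chromosome 20, 38055037 to 38057101), which stood at 237 FPKM in the mock library and 2.34 FPKM in the inoculated library, 101-fold lower and a log2 ratio of -6.15. Next was Glyma.02G161300 (chromosome 2, 19689022 to 19689186), at 33.0 FPKM in the mock library and listed at 0 in the inoculated library. With a pseudocount of 5 the log2 ratio of Glyma.02G028600 was 4.74, below the 5.13 of Glyma.20G169200. With a pseudocount of 0.1 that of Glyma.02G161300 was -8.37, below the -6.60 of Glyma.20G142000. The model of Glyma.02G161300 spans 165 bp, and 54.8% of the 157 expressed genes with spans under 200 bp were listed at 0 in 1 of the libraries.

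**Figure D2:**
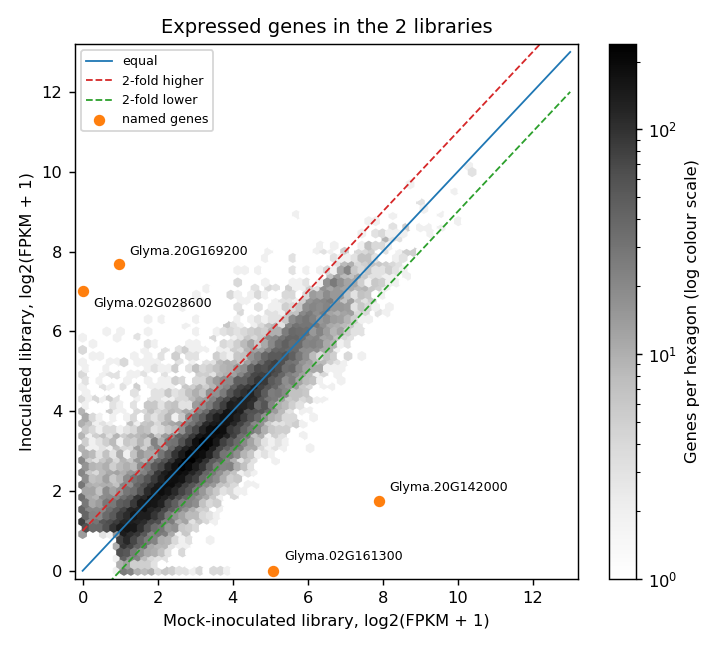
log2(FPKM + 1) of the 34062 expressed genes in the mock library (x axis) and the inoculated library (y axis), shaded by the number of genes per hexagon on a log scale, with lines of equality and of 2-fold difference. Orange points are the 4 named genes, and the cloud extends further above the upper dashed line than below the lower one.

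The most abundant transcripts included both higher and lower genes. Of the 100 genes with the highest FPKM in the mock library, 21 were lower in the inoculated library and 0 were higher, with a median log2 ratio of -0.51. Of the 100 genes with the highest FPKM in the inoculated library, 37 were higher and 8 lower, with a median log2 ratio of 0.55. The 2 sets shared 58 genes. Because each set was picked on 1 of the libraries compared, its median leans towards that library with no change at all. The 2757 higher genes took 3.65% of all FPKM in the mock library and 17.4% in the inoculated library. The 1954 lower genes took 12.6% in the mock library and 4.57% in the inoculated library. These 2 sets were picked on the difference itself, so the direction of these changes in share is fixed by the choice.

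Genes that were higher in the inoculated library lay side by side more often than in shuffled calls. There were 35 runs of at least 4 neighbouring expressed genes that were all higher, and 28 of the runs covered under 100 kb. They held 174 of the 2757 higher genes, on 18 chromosomes. Shuffling the calls within chromosomes gave a mean of 1.49 such runs and at most 7 in 1000 shuffles. Lower genes formed 1 run, of 4 genes on chromosome 14 (2853746 to 2877988), where shuffles gave a mean of 0.363 and at most 3. Pairs of neighbouring expressed genes exceeded every shuffle in both directions. There were 524 pairs with both genes higher against at most 265, and 169 with both lower against at most 148. With no filter on low values, so that unexpressed genes break a run, there were 17 runs of higher genes, and with a pseudocount of 5 there were 13.

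The longest runs held 10 expressed genes each. On chromosome 18, from 2507213 to 2549732, all 10 gene models of a 42.5 kb region were listed at 0 in the mock library and lay between 3.51 and 37.6 FPKM in the inoculated library. On chromosome 9, from 38660406 to 38813412, 8 of the 10 expressed genes were listed at 0 in the mock library, and the inoculated values ranged from 2.80 to 66.4 FPKM. The gene at 66.4 FPKM had 13.4 FPKM in the mock library. A stretch of 7 neighbouring genes at 0 in the mock library lay between 2.80 and 13.4 FPKM in the inoculated library. A run of 8 expressed genes on chromosome 2 (2497530 to 2627188) contained Glyma.02G028600; its members reached at most 35.8 FPKM in the mock library, ranged from 5.52 to 3616 FPKM in the inoculated library and had a median log2 ratio of 4.27. On chromosome 15, from 13455016 to 13593935, the run held 7 expressed genes. Of these, 6 were listed at 0 in the mock library and lay between 1.03 and 2.79 FPKM in the inoculated library. The remaining gene had 6.15 FPKM in the mock library and 18.8 FPKM in the inoculated library. In all these regions the values do not tell absent transcripts from failed estimates in the mock library, and the runs were not recomputed without genes listed at 0.

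Some runs held abundant transcripts. The 4 genes of a run on chromosome 7 (42331425 to 42356707) added up to 462 FPKM in the mock library and 7351 FPKM in the inoculated library. The 5 genes of a run on chromosome 17 (2203480 to 2223193) added up to 604 FPKM and 5404 FPKM, with log2 ratios between 2.87 and 3.79. On chromosome 13, 4 genes between 28730694 and 28772001 added up to 81.3 FPKM and 1181 FPKM, of which 1 gene held 56.5 FPKM and 813 FPKM. A second region of that chromosome (35861715 to 35893009) held 5 expressed genes that were all listed at 0 in the mock library and lay between 26.9 and 43.9 FPKM in the inoculated library. There too, absent transcripts and failed estimates cannot be told apart. On chromosome 8, 4 genes between 45574659 and 45596599 added up to 20.9 FPKM and 1075 FPKM, of which 1 gene held 18.5 FPKM and 979 FPKM. Neighbouring genes can be near-identical copies, and how reads shared by such copies were counted is not given in the sources used here.

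**Figure D3:**
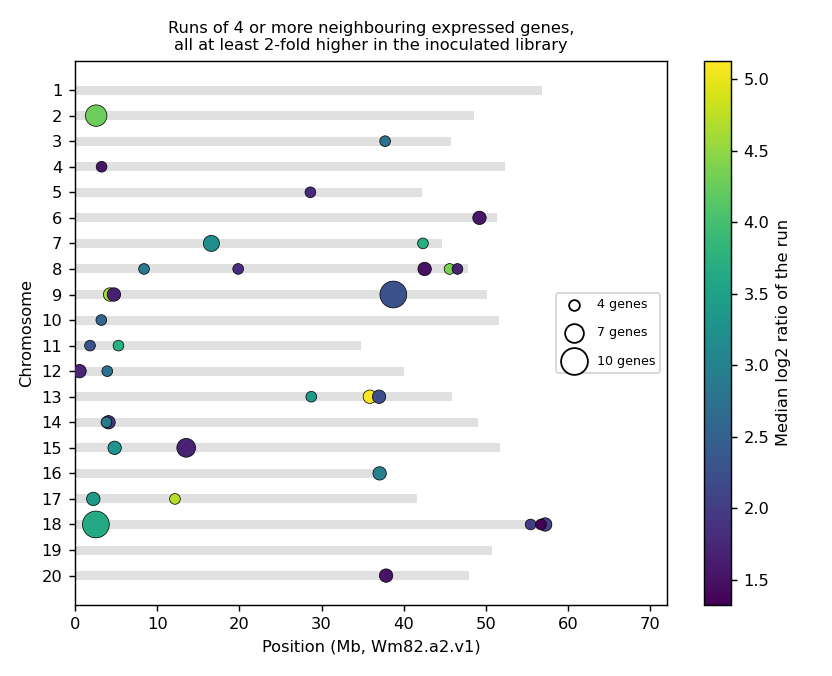
Positions of the 35 runs of higher genes along the 20 chromosomes (x axis in Mb, y axis chromosome number; grey bars end at the last gene of each chromosome), with circle area growing with the number of expressed genes and colour giving the run's median log2 ratio. The 10-gene runs lie on chromosomes 9 and 18, and the highest median, 5.13, belongs to the run on chromosome 13 that starts at 35861715.

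The 2 chromosome windows were set from memory, and no source used here places the study's loci in them. They had medians on opposite sides of 0. In the chromosome 3 window (3341419 to 5010884), 51 of 101 genes were expressed; 2 were higher, 6 were lower and 43 lay within 2-fold. Its median log2 ratio of -0.36 stood at the 0.02 percentile of 10000 random lists matched on expression, and at the 0.561 percentile of stretches of as many neighbouring expressed genes. Its counts were less extreme among these stretches, at the 19.0 percentile for higher genes and the 93.9 percentile for lower genes. Subtracting the trend with span gave a median of -0.27. The higher genes lay at 4274744 to 4278897 (2.55 FPKM mock, 10.4 FPKM inoculated) and at 4432910 to 4435002 (1.42 and 8.65 FPKM). The lower gene with the largest difference lay at 4402746 to 4408323, with 19.9 FPKM in the mock library and 6.33 FPKM in the inoculated library. With a pseudocount of 5 there were 2 higher genes and 1 lower gene and the median was -0.15, with a pseudocount of 0.1 there were 5 higher and 13 lower genes, and with unexpressed genes kept the median was 0. At a 4-fold threshold there were 0 higher and 0 lower genes.

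In the chromosome 16 window (36841786 to 37394260), 52 of 81 genes were expressed; 9 were higher, 2 were lower and 41 lay within 2-fold. Its median log2 ratio of 0.16 stood at the 99.05 percentile of the matched random lists and at the 97.7 percentile of neighbouring stretches. Among these stretches its counts stood at the 95.5 percentile for higher genes and the 32.3 percentile for lower genes. Of the 9 higher genes, 5 formed a run from 37057124 to 37085742, in which the mock values were at most 4.66 FPKM and the inoculated values ranged from 2.04 to 57.2 FPKM. The member with the highest log2 ratio, 3.36, lay at 37071149 to 37072040 and had 4.66 FPKM in the mock library and 57.2 FPKM in the inoculated library. The 2 lower genes lay at 36968641 to 36973853 (95.6 FPKM mock, 44.5 FPKM inoculated) and at 37349818 to 37353883 (24.9 and 11.7 FPKM). Rescaling to the median ratio left 1 of these calls and subtracting the trend with span left 0, and the window's median was 0 when unexpressed genes were kept. With a pseudocount of 5 there were 5 higher genes and 1 lower gene and the median was 0.081. With a minimum of 5 FPKM the median was 0.39.

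**Figure D4:**
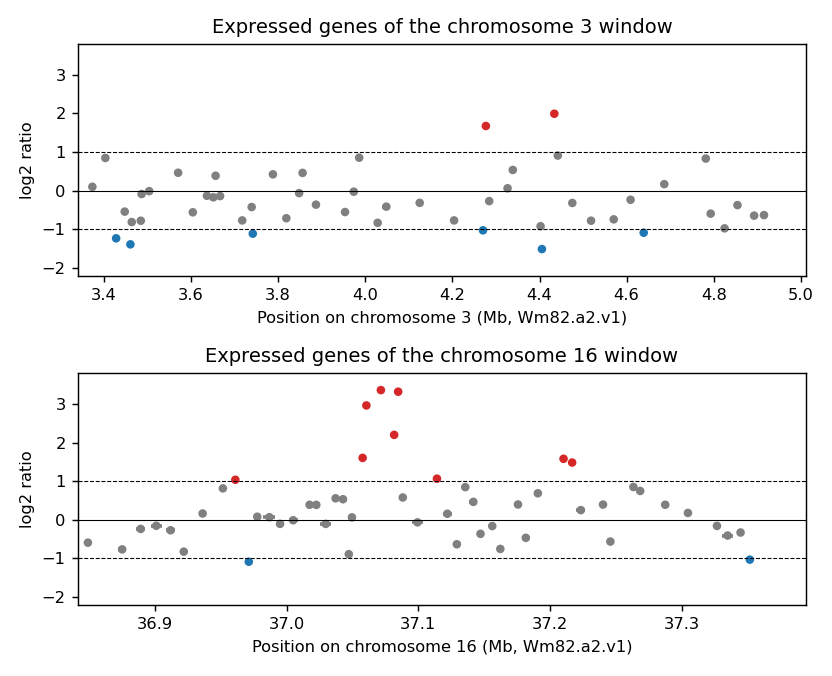
log2 ratio (y axis) of each expressed gene against its position in Mb (x axis) in the chromosome 3 window (51 genes) and the chromosome 16 window (52 genes), with dashed lines at 2-fold, higher genes in red and lower genes in blue. The 5 neighbouring higher genes of the chromosome 16 window lie between 37057124 and 37085742.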

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

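The alternatives that leave out spans under 500 bp, subtract the trend with span or use neighbouring stretches, and those for the runs, were chosen after the data were seen. Of 103 alternative values, 71 stayed close to the reported one (within 1.5 times for counts, medians and linear ratios, and on the same side of 50 for the windows' percentiles) and 32 moved. A change of sign was found for 0 of them, but this was largely fixed in advance. Counts have no sign, and a pseudocount cannot change the sign of a gene's log2 ratio. Window medians that became 0 were counted as moved. A pseudocount of 5 gave 1349 higher and 687 lower genes, 13 runs, 1 lower gene and a median log2 ratio of -0.15 on chromosome 3, and 5 higher genes, 1 lower gene and a median of 0.081 on chromosome 16. A pseudocount of 0.1 gave 3152 lower genes, with 5 higher and 13 lower in the chromosome 3 window; it left higher genes at 3529. By construction a larger pseudocount shrinks every log2 ratio. The 4-fold threshold gave 972 higher and 164 lower genes, 13 runs, 0 higher and 0 lower on chromosome 3, and 4 higher and 0 lower on chromosome 16. Without a filter there were 17 runs and both window medians were 0, because unexpressed genes then enter the windows and break the runs; the gene counts cannot change, since no gene under 1 FPKM can reach 2-fold on this scale. A minimum of 5 FPKM gave window medians of -0.24 on chromosome 3 and 0.39 on chromosome 16. Rescaling to the median left 1 lower gene on chromosome 16 and subtracting the trend with span left 0, since their log2 ratios, -1.08 and -1.03, lay near the threshold: the first correction raised the gene at -1.03 past it and the second raised both. The chromosome 3 percentile was 0.01 without matching and 0.561 among neighbouring stretches. The 2 rescalings shifted log2 ratios by 0.036 and -0.067, and higher genes made up 61.3% and 53.5% of all calls against 58.5% as reported. The alternatives set for gene lists by product name were not run, because no list could be filled. No paired analysis was possible because each condition has 1 library. Depth limits the low genes most: a gene at 0 in the shallower mock library need not be absent.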

Other observations

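The comparisons of chromosomes, stretches at 0, strong changes, span and runs below were chosen after the values were seen. For strong changes, span and runs the bound was set before the test's value was computed, and for chromosomes and stretches at 0 no bound was set. Chromosome 18 had the highest share of higher genes, 11.3% of 1684 expressed genes (191 genes). Its share stood at the 99.4 percentile of 10000 circular shifts of the calls, but in 10.8% of the shifts at least 1 of the 20 chromosomes was as high. Chromosome 4 had the lowest share, 6.54% of 1605 expressed genes. Chromosome 17 had the highest share of lower genes, 7.30% of 1699 expressed genes, at the 97.3 percentile for that chromosome. It was picked as the highest of 20 chromosomes. How often any chromosome was as high in the shifts was not computed for lower genes.

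Stretches of neighbouring genes that were listed at 0 in a single library occurred in the mock library alone: 4 stretches of at least 4 expressed genes against 0 in the inoculated library, with 451 and 113 expressed genes at 0. The stretch on chromosome 18 (2507213 to 2549732) was flanked by expressed genes at 10.6 and 1.25 FPKM in the mock library, and these stood at 7.56 and 0.133 FPKM in the inoculated library. The stretch on chromosome 13 (35861715 to 35893009) was flanked by genes at 10.1 and 24.7 FPKM in the mock library. The other stretches lay on chromosome 9 (38692452 to 38807557, 7 genes) and chromosome 15 (13455016 to 13538711, 6 genes). The table does not tell absent transcripts from failed estimates.

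The excess of strong increases over strong decreases was 972 to 164 at 4-fold. After centring on the median ratio, the higher to lower ratio was 6.47 (1003 to 155 genes). That centring shifted log2 ratios by only 0.036, so its outcome was close to fixed in advance. A scaling difference of that size does not account for the excess. Rescaling without the 100 most abundant genes was not applied at 4-fold. At 2-fold it gave 2551 higher and 2216 lower genes against 2757 and 1954 as reported. Counting noise at low values in the shallower mock library is argued against as the whole cause, because among genes with a mean of 20 FPKM or more the ratio was 6.67 (327 to 49 genes), where at most 1.5 had been set for noise. What stays open is whether inoculation or another difference between these plants and libraries gave the excess, since each condition has 1 library; no biological explanation was tested.

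Genes with short spans were called more often. In the shortest 20% by span 19.0% of expressed genes were higher, against 2.69% in the longest 20%, a ratio of 7.08, and the share of lower genes had a ratio of 2.86. Counting noise in genes with low FPKM is argued against as the whole cause of the excess of higher genes. Among genes with a mean of 20 FPKM or more the ratio was still 3.46 (17.3% against 5.01%), though it was smaller there. This minimum does not bound noise in very short models, where few reads can give a high FPKM. The ratio was not recomputed without them. For lower genes the ratio fell to 1.90 under the same minimum, so noise is not excluded for them. A trend with span that shifts all genes existed, with a median log2 ratio of 0.089 in the shortest 10% and -0.15 in the longest 10%. Subtracting it left a ratio of 5.23 for higher genes. The trend is small against the log2 threshold of 1, so this outcome was close to fixed in advance. A shift of that size does not account for the excess. No biological explanation was tested. Noise may still account for the extreme decreases, since 6 of the 10 genes with the lowest log2 ratio spanned under 200 bp and were listed at 0 in the inoculated library.

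Higher genes lay next to each other more often than shuffled calls did, with 35 runs against at most 7 in 1000 shuffles. Overlapping gene models that share reads are argued against as the whole cause: among neighbours more than 1 kb apart, 477 pairs were both higher, 2.37 times the mean of the shuffles. Lower genes showed a smaller excess over the same spacing, 146 pairs or 1.45 times the shuffle mean, and the difference between the directions was not tested. Reads shared between near-identical neighbouring copies stay open, because gene sequences were not used here, and no biological explanation was tested.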
